A study of Mus musculus with 6 samples.

How the data were processed

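AtT-20 cells, a mouse pituitary tumour line of corticotroph origin that makes pro-opiomelanocortin, were given 20 nM siRNA repeatedly over 8 days, per the labels. The siRNA was directed either at Dnmt1 or was a non-targeting control. Total RNA was taken on day 8 and hybridised, biotin-labelled, to 1 Affymetrix mouse array per sample. Per the labels the whole procedure was carried out 3 times independently, which gave 3 knockdown arrays and 3 control arrays that share the repeat numbers 1 to 3. The groups were taken from the labels alone.

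The deposited table holds 1 intensity per probe set and array on a linear scale, and per the submitters' processing notes it was made with GCOS, the Affymetrix operating software. The version, algorithm settings, scaling target and detection calls are not given in the sources used here. The deposited intensities were not on a common scale. Median signals per array were 20.3 for knockdown 1, 19.8 for control 1, 36.3 for knockdown 2, 33.2 for control 2, 22.8 for knockdown 3 and 24.0 for control 3. The 2% trimmed means were 73.6, 70.2, 140.1, 140.2, 83.3 and 93.4 in the same order. They differed by more than 10%, which was the condition fixed before the data were examined for centring each array, so each array was scaled to the same median log2 value. After this scaling the 2% trimmed means still differed by more than 10%, from 89.9 for control 1 to 107 for control 2. The 3'/5' signal ratios of actin were 1.19 to 1.40 over the 6 arrays and those of Gapdh 0.777 to 0.858. No 2 arrays held identical values. The brightest probe sets are compressed, as a check made after the data were seen showed. Deposited signals of repeat 2 exceeded those of repeats 1 and 3 by a median log2 of 0.866 for probe sets with mean signals of 200 to 500, but by 0.380 at 4000 to 6000 and 0.169 above 7000. Differences of such bright probe sets are understated and follow the scale factors more than those of dimmer ones. The number of arrays limits the precision of every value below.

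The pseudocount was 5.29, the 20th percentile of all deposited values, and every difference is on the log2(scaled signal + pseudocount) scale, which understates changes of dim probe sets. The table lists 45101 probe sets, of which 64 are controls. The 27022 probe sets with a mean scaled signal at or above the 40th percentile, 16.8, were tested, and 18015 dimmer ones were left out. Gene symbols came from a platform annotation of the array, checked against a mouse gene table of assembly GRCm38.p6, which changed 0 symbols and served for names and gene order only. Apart from the controls, 34945 probe sets had 1 symbol, 932 had several and 9160 had none, and only those with 1 symbol were named. The tested probe sets with 1 symbol numbered 22819, for 13477 genes. Where a gene had several probe sets, the brightest stood for it in the gene lists.

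Knockdown was compared with control by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend, two-sided), with the Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. The fit without the repeat number was the design fixed beforehand, and the fit with the repeat number as a block, called the paired fit below, was its stated alternative. The deviations of same-numbered arrays from their group means correlated at 0.173, 0.231 and 0.257 across probe sets, against -0.179 to -0.0283 for arrays of different number. Each same-numbered correlation was over 0.1, so the repeat numbers pair the arrays, and the paired value stands beside each result whose call it changes. Because the labels describe independent repeats, the p-values measure the spread between separate rounds of treatment.

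A probe set was counted as separated when the lowest value of 1 group was at least 1.5 times the highest value of the other. The rule for the genes named, also fixed beforehand, took Dnmt1, Pomc and any other methylation gene past the threshold. It then took up to 15 genes in each direction by size of difference, from those past the threshold and otherwise from separated probe sets, counting a gene only if its brightest probe set was separated. For each gene list it took the up to 4 members with the smallest unadjusted p. Genes past the threshold in the paired fit alone were named after their values were seen. The 24 gene lists were written before the data were examined and hold 789 different genes, of which 565 were tested. List shifts were tested with camera at a preset correlation of 0.01, adjusted over the 24 lists, with an estimated correlation and with fry as alternatives. Random lists of the same size, matched on mean signal, were drawn 10000 times per list. Dnmt1 was also tested by an exact permutation test, in which 3 arrays against 3 cannot give a two-sided p below 0.1.

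The fits were tested on simulated data built from the real means, variances and repeat structure, with 200 probe sets changed by known folds in each of 10 simulations of 27022 probe sets. With variances drawn from the fitted prior, the fit without the block recovered 0.4% of 1.5-fold, 13.2% of 2-fold, 52.0% of 3-fold and 65.8% of 4-fold changes. The paired fit recovered 1.4%, 17.2%, 56.4% and 68.4%. Of the calls, 1.50% and 4.27% were false. With each probe set's shrunken variance taken as true, the paired fit recovered 9.4%, 46.2%, 78.2% and 84.8%, and 10.0% of its calls were false, above its nominal 5%. Camera with the preset correlation called both of 2 simulated shifted lists and 0 of 22 unchanged ones. With an estimated correlation it called 0 of the 2 shifted lists. The simulated genes of a list shared no noise, so this run cannot show how often the preset correlation calls unchanged real lists. The lists that camera called in the real data without the block had estimated correlations of 0.05 to 0.27.

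Alternatives were other pseudocounts, filters, scalings, variance models and thresholds, the block, a fit without each array and the removal of probe sets whose design allows cross-hybridisation. Scaling to a common trimmed mean, the paired fit without each repeat and the paired fit under each other setting were added after the data were seen. statmod 1.5.0 served the robust fit. Figures and gene order were made in Python 3.11.15 with matplotlib 3.10.9 and pandas 2.3.3. Scanner images, probe-level values, siRNA sequences, protein and DNA methylation were not analysed here.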

Results

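Transcript abundance was measured in AtT-20 mouse corticotroph tumour cells after 8 days of repeated transfection with siRNA against Dnmt1, the enzyme that copies DNA methylation to newly replicated strands, or with a non-targeting siRNA. There were 3 arrays per group, 1 of each group from every independent repeat. The comparison asks which transcripts become more or less abundant when Dnmt1 is reduced, a way to look for genes that DNA methylation holds silent in pituitary tumour cells.

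Dnmt1 transcript was lower in the knockdown in all 3 repeats and was not removed. On its brightest probe set the scaled signal was 219 ± 79.6 in the knockdown and 620 ± 80.4 in the control (SD, n = 3), a log2 difference of -1.54 (SE 0.24). The knockdown arrays of repeats 1, 2 and 3 held 39.6%, 20.2% and 48.6% of the signal of their paired controls, a mean of 36.1% ± 14.5 (SD, n = 3). The other 2 Dnmt1 probe sets differed by -1.81 and -1.75. Knockdown and control signals did not overlap on any of the 3 probe sets, which gives the smallest p that an exact permutation test of 3 against 3 allows, 0.1. Without the block the limma adjusted p of the brightest probe set was 0.151, and in the paired fit Dnmt1 fell with an adjusted p of 0.0211. Without knockdown array 3, from the repeat with the most remaining Dnmt1, the unpaired difference was -1.79 with a limma adjusted p of 0.0432.

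No other gene of the DNA methylation machinery passed the threshold in either fit. Of the 21 tested members of that list, 10 had higher and 11 lower values in the knockdown. The differences after Dnmt1 with the smallest p were those of Zbtb33, encoding the methyl-CpG binding protein Kaiso, at -0.59 (SE 0.35), of the chromatin remodeller Hells at -0.43 (SE 0.28) and of Gadd45b at 0.27 (SE 0.18). The de novo methyltransferase genes Dnmt3a and Dnmt3b differed by 0.04 (SE 0.32) and -0.06 (SE 0.29) on their brightest probe sets, and Uhrf1, which brings Dnmt1 to replicating DNA, by 0.11 (SE 0.20). Dimmer probe sets were at 0.34 and -0.28 for Dnmt3a and at 0.12 for Dnmt3b. Adjusted over the list alone, 0 members were higher and 1, Dnmt1, was lower. The median of the list was -0.01, and it was above 0 under the 3 other scalings.

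**Figure D1:**
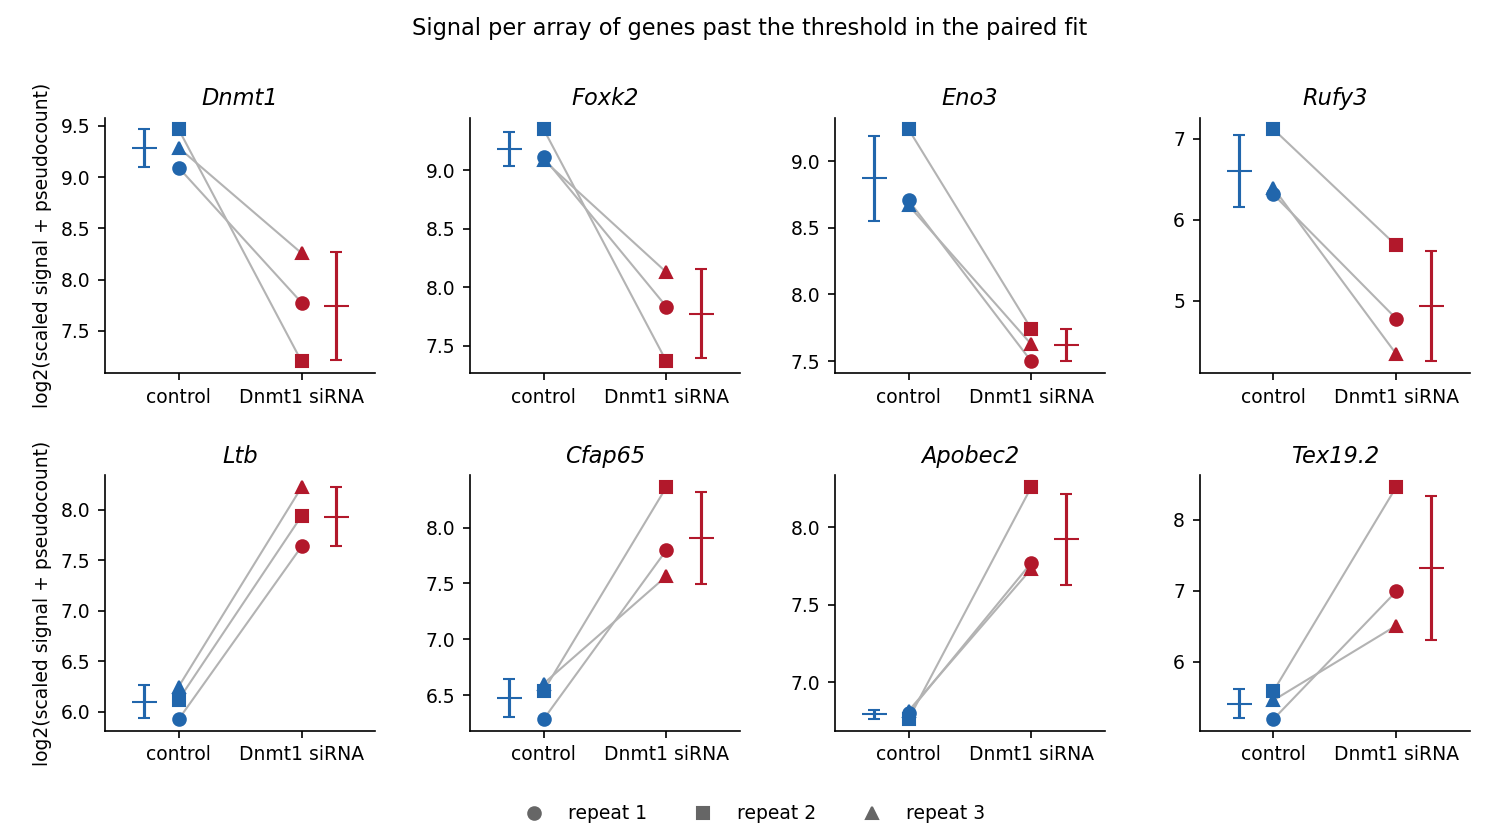
Signal of 8 genes on each array, as log2(scaled signal + pseudocount), with grey lines joining the knockdown and control array of the same repeat, and bars showing the mean ± SD (n = 3). The 8 genes are paired calls whose brightest probe set was separated. That the 3 knockdown points lie apart from the 3 control points in all 8 panels therefore follows from this choice. Paired calls without such a probe set, for example Vapa and Txnrd1, are not shown. Dnmt1 was lower by 1.54 and Ltb higher by 1.84 on the log2 scale. Under trimmed mean or quantile scaling only Eno3 and Ltb of the 8 stay past the paired threshold.

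Beyond Dnmt1, the paired fit called a short list of genes in each direction. Foxk2, encoding a forkhead transcription factor, fell on 3 probe sets by 1.41, 1.13 and 1.17 on the log2 scale (paired SE 0.18, 0.15 and 0.17), to a scaled signal of 219 ± 57.5 from 578 ± 60.5 on the brightest (SD, n = 3). Eno3, the muscle form of the glycolytic enzyme enolase, fell by 1.25 (paired SE 0.15). Ltb, encoding lymphotoxin beta of the tumour necrosis factor family, rose by 1.84 (paired SE 0.17), from 63.6 ± 7.68 to 243 ± 50.1 (SD, n = 3). The paired limma adjusted p was 0.0197 for the brightest Foxk2 probe set, 0.0141 for Eno3 and 0.00412 for Ltb, and each difference had the same direction in 3 of 3 pairs. Without the block the limma adjusted p of Ltb was 0.0608, and it was 0.0208 with trimmed mean scaling and 0.0444 with quantile scaling.

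The other paired calls were named after their values were seen, except where the rule named them. Cfap65, a gene of cilia and flagella, rose by 1.43, Apobec2, of the cytidine deaminase family, by 1.13, and Tex19.2, a germline gene, by 1.90 (paired limma adjusted p = 0.0211, 0.0437 and 0.0429). Nfkbia, encoding the inhibitor of NF-kappa-B, rose by 0.64 on 1 probe set (adjusted p = 0.0491 in the paired limma fit), and its 4 other probe sets had differences of 0.44 to 0.84. Vapa, of the contact sites between the endoplasmic reticulum and other membranes, fell by 0.93 and 1.10 on its 2 probe sets, the small GTPase Cdc42 by 0.78 and the cytosolic thioredoxin reductase Txnrd1 by 0.61 (paired adjusted p = 0.0429, 0.0429, 0.0429 and 0.0491 by limma). The 3 other Cdc42 probe sets were at -0.49 to -0.71 and the 2 other Txnrd1 probe sets at -0.49 and -0.62. Rufy3 fell by 1.67 on 1 probe set, while its 3 others were at -0.07, -0.04 and 0.40. E2f5 rose by 2.19 on 1 probe set and Sirt5, a mitochondrial deacylase, by 2.84 on its dimmer one, whereas the remaining E2f5 probe sets were at 0.04 and 0.09 and the other Sirt5 probe set at 0.73. The 2 remaining Foxk2 probe sets, both dimmer, were at 0.17 and -0.09.

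In all, limma without the block called 0 probe sets, and the paired fit called 23, of which 8 were higher and 15 lower, standing for 14 named genes, 7 in each direction. At an unadjusted p under 0.05 there were 1025 probe sets without the block, 357 higher and 668 lower. That is less than a share of 0.05 of the 27022 tested, the share expected if no probe set changed. With trimmed mean scaling 607 were higher and 501 lower, so the balance of directions depended on the scaling. The median difference over all tested probe sets was -0.0555, and 0.0019 with trimmed mean scaling. The paired count depended on the scaling, on the variance trend and on repeat 3: it was 3 with trimmed mean scaling and 4 with quantile scaling, where Eno3, Ltb and Nfkbia were the genes called, 0 without the trend and 266 without repeat 3. It was 41 without repeat 1 and 41 without repeat 2. Without the block, leaving out knockdown array 1 gave 2 calls, Ltb and Napb, and leaving out knockdown array 3 gave 4 calls, all lower. The unmoderated linear model called 0 with and without the block.

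A count that needs no model found 56 separated probe sets, 21 higher and 35 lower. In the simulated data the same rule separated 37 unchanged probe sets per simulation with variances drawn from the fitted prior. With shrunken variances it separated 22.3. Chance alone parts 3 arrays from 3 for 10% of probe sets before any fold is asked. Leaving out any 1 of the 6 arrays, for example knockdown array 1 or control array 2, gave between 168 and 243 separated probe sets. Such a rise follows from the rule, since fewer arrays have to be parted. All genes named from this count are given as values, since none passed the threshold without the block. Among genes whose brightest probe set was separated, the largest difference upwards was that of Tex19.1, a germline and placental gene and close paralog of Tex19.2, with a difference of 2.35 (SE 0.54) and signals of 276 ± 286 against 33.9 ± 5.50 (SD, n = 3), so its size varied strongly between repeats. The paralogs' signals are uncertain for want of probe-level values. Gsdmd, encoding the pore-forming protein of pyroptosis, differed by 2.24 (SE 0.36), from a control signal of 6.42 ± 0.982 (SD, n = 3) close to the pseudocount, and the calcium-binding protein gene S100a6 by 2.19 (SE 0.61), from a control signal of 3.06 ± 1.85 (SD, n = 3) below the pseudocount, so that the sizes of both differences depend on it. The testis gene Oaz3 differed by 1.79 (its other probe set by 0.34) and the forkhead factor gene Foxo4 by 1.53 (its other probe set by -0.74). 4930455D15Rik differed by 1.501, Tex48 by 1.38, the ciliary kinesin gene Kif7 by 1.19 and Fxyd3 by 1.16. Except for Fxyd3, the control signals of these genes were 9.11 to 11.7, not far above the pseudocount, so their sizes depend on it too. Together with Tex19.2, Ltb, Cfap65 and Apobec2, the genes given here from Tex19.1 to Fxyd3 were all 13 genes whose brightest probe set was separated upwards.

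Of 17 such genes in the other direction, the 15 with the largest differences included Dnmt1, Foxk2, Eno3 and Rufy3. Napb, a SNAP protein gene of membrane fusion, differed by -1.95 (SE 0.41), with its 4 dimmer probe sets at -0.42 to -0.71. The tyrosine kinase gene Tec differed by -1.83, the lysophospholipid acyltransferase gene Lpcat4 by -1.79, Ankrd23 by -1.62 and the trefoil factor gene Tff3 by -1.34. Kcnma1, encoding a calcium-activated potassium channel, differed by -1.30, the orphan nuclear receptor gene Nr4a3 by -1.29, Apoc1 by -1.26, AI839979 by -1.19, Olfr288 by -1.14 and the G protein subunit gene Gnao1 by -1.10. The brightest of these in the control apart from the paired calls was Gnao1, at 152 ± 42.4 (SD, n = 3), and its 2 other probe sets were at -0.32 and -0.19. The other Kcnma1 probe set was at -0.27 and the other Nr4a3 probe set at -0.01. The knockdown signal of Tec, 5.13, was below the pseudocount. Those of Tff3, Apoc1, Nr4a3, Ankrd23 and Olfr288 were 8.32 to 13.0, not far above it. The sizes of the differences of these genes therefore depend on the pseudocount.

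Interferon-stimulated genes shifted upwards as a group. The median difference over all tested probe sets was itself -0.06, so list medians and counts of lower members near that value differ little from the rest of the array. Of 33 tested members 24 had higher and 9 lower values, with a median log2 difference of 0.29 and a camera adjusted p of 9.1e-08. Over 21 alternatives the median ran from 0.15 to 0.35. With an estimated correlation the call was lost (adjusted p = 0.343 with an estimated correlation, 0.0143 before adjustment). Ifitm3, a membrane protein gene that restricts virus entry, differed by 1.54 (SE 0.60), Irf9 of the interferon signalling complex by 0.81 (SE 0.25), the nucleic acid sensor gene Zbp1 by 0.81 (SE 0.24) and Ifi35 by 0.51 (SE 0.14). The size for Ifitm3 rests mostly on repeat 3 (0.46, 1.06 and 3.09 in repeats 1 to 3). Its log2 value on control array 3 was 2.66, against 5.29 on control arrays 1 and 2. Among the 9 members with lower values were Rsad2 at -0.89 (SE 0.52), Ifit3 at -0.58 (SE 0.52), Ifit1 at -0.52 (SE 0.44) and Ccl5 at -0.51 (SE 0.26). No member passed over all probe sets in either fit. Adjusted over the list alone, 0 passed without the block and 9, all higher, passed in the paired limma fit: Ifi35, Zbp1, Irf9, Ifitm3, Xaf1, Ifi27, Ifitm1, Usp18 and Oas2. With fry, which asks whether the members move on balance 1 way, the list had an adjusted p of 0.372 without the block and 0.044 in the paired fit.

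Genes of MHC class I antigen presentation were also shifted upwards by camera (15 tested, median 0.16, adjusted p = 0.00065), a call lost with an estimated correlation (adjusted p = 0.633 with an estimated correlation). Only 8 of the 15 had higher values. These were Tapbp, encoding tapasin of the peptide loading complex, at 0.84 (SE 0.21), Psmb9 at 0.59 (SE 0.23), Psme1 at 0.44 (SE 0.15), Tap2 at 0.42 (SE 0.20), Psmb10, B2m, Tap1 and Psmb8, while among the others the heavy chain genes H2-K1 and H2-D1 were at -0.03 and -0.02 and Calr, Canx and Pdia3 at -0.20, -0.18 and -0.11. Scaling turned the sign of some of these small values. The list median ran from 0.07 to 0.30 over 21 alternatives. Over all probe sets 0 members passed in either fit. Adjusted over the list alone, 1 member, Tapbp, was higher without the block, and 3 were higher in the paired fit.

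**Figure D2:**
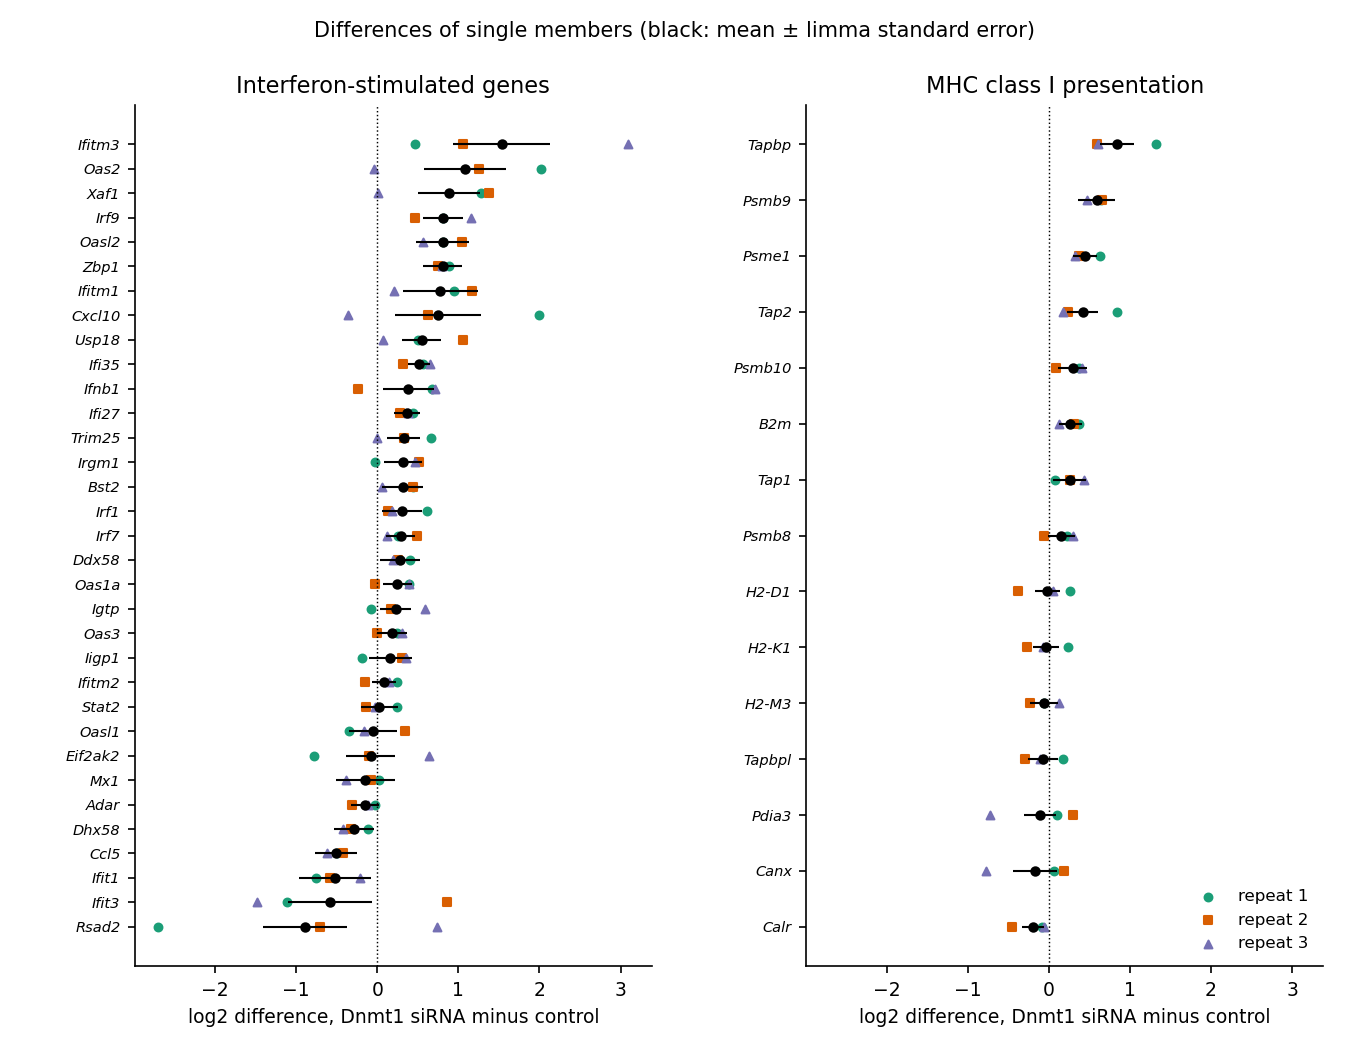
Log2 difference, knockdown minus control, of each tested member of the interferon list (33 genes) and the MHC class I list (15 genes). Black points are means with limma standard errors and coloured points are the 3 repeats; 24 of the 33 interferon genes and 8 of the 15 MHC class I genes lie above 0, with the members near 0 open to the scaling.

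Of the other lists past the camera threshold upwards, metallothioneins and oxidative stress genes (20 tested, 12 with higher and 8 with lower values, median 0.15, adjusted p = 0.0453) lost their call with an estimated correlation (adjusted p = 0.633 with an estimated correlation). Mt2, encoding a metal-binding metallothionein, differed by 0.45 (SE 0.13), the catalase gene Cat by 0.95 (SE 0.32) and Gclm of glutathione synthesis by 0.43 (SE 0.30), while Txnrd1 was lower as given above. In repeats 1 to 3 Cat was at 1.14, 1.57 and 0.13 and Gclm at 0.54, 0.73 and 0.01, so both hardly differed in repeat 3. Over all probe sets 0 members passed without the block and 1, Txnrd1, in the paired fit. Adjusted over the list alone, 0 were higher and 1 lower without the block, and 2 were higher and 1 lower with it. Markers of fibroblasts and matrix (18 tested, median 0.19, adjusted p = 0.00528) had higher values in 14 members, and their call was lost too (adjusted p = 0.633 with an estimated correlation). The examples are all dim: Pdgfra at 1.26 (SE 0.47), S100a4 at 0.84 (SE 0.53) and Col6a1 at 0.68 (SE 0.34), against Mmp2 at -0.64 (SE 0.35). No member passed, adjusted over the list alone or over all probe sets. Over 21 alternatives the fibroblast median ran from 0.02 to 0.30 and the metallothionein median from 0.01 to 0.21. The metallothionein call also ended without scaling, without the trend, without cross-hybridising probe sets and without knockdown array 1 or 2 or control array 2 or 3 (adjusted p = 0.0875 to 0.413), and the fibroblast call ended with quantile scaling, with the stricter filter and without control array 2 or knockdown array 3 (adjusted p = 0.0535 to 0.224).

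Genes of secretory granules and peptide processing shifted downwards (26 tested, 20 with lower values, median -0.22, camera adjusted p = 0.00065), a call lost with an estimated correlation (adjusted p = 0.633 with an estimated correlation). Sv2a, a vesicle membrane glycoprotein gene, differed by -0.88 (SE 0.21), the calcium sensor gene Syt7 by -0.60 (SE 0.16), the vesicle GTPase gene Rab3a by -0.49 (SE 0.13) and the granule protein gene Ptprn by -0.49 (SE 0.17). The most abundant granule cargo and enzyme genes, some of them compressed by their brightness, lay nearer 0, with Chga at -0.10 (SE 0.18), Chgb at 0.04 (SE 0.19), Cpe at -0.08 (SE 0.14) and Pcsk1 at 0.08 (SE 0.21). Over all probe sets 0 passed in either fit. Adjusted over the list alone, 3 were lower without the block, Sv2a, Syt7 and Rab3a, and 5 were lower with it. Genes of oxidative phosphorylation had lower values in 44 of 45 members, with a median of -0.15 and a camera adjusted p of 1.0e-05, a call lost with an estimated correlation (adjusted p = 0.633 with an estimated correlation). All probe sets of similar brightness, 2000 to 4000 in deposited signal, had a median of -0.105. Sdhc differed by -0.30 (SE 0.13), Ndufa10 by -0.26 (SE 0.13), Ndufb5 by -0.25 (SE 0.12) and Ndufv1 by -0.32 (SE 0.17), and none passed over all probe sets or adjusted over the list alone. The oxidative phosphorylation median lay at -0.06 to -0.12 under the 3 other scalings, and without knockdown array 2 it was -0.07 with an adjusted p of 0.154. Its camera call held under those scalings (adjusted p = 0.0037 trimmed mean, 0.00243 quantile and 0.00995 without scaling), each time lost with an estimated correlation (adjusted p = 0.913, 0.530 and 0.964 with an estimated correlation).

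Cytosolic ribosomal protein genes did not pass without the block (31 tested, median -0.08, camera adjusted p = 0.386), and their paired value passed at 0.034, lost with an estimated correlation (adjusted p = 0.789 with an estimated correlation). Their median turned to 0.02 under quantile scaling, and with a median deposited signal of 4807 most members lie where the arrays compress differences. Rpl4 differed by -0.19 (SE 0.15), Rps10 by -0.18 (SE 0.17), Rpsa by -0.13 (SE 0.14) and Rps28 by -0.15 (SE 0.17), and 0 members passed adjusted over the list alone. Across the lists, camera called 6 of 24 without the block, 4 up and 2 down, and 7 in the paired fit. With an estimated correlation it called 0 in either fit, and fry called 0 without the block and 1 with it.

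Pomc, the precursor gene of adrenocorticotropin and the hormone gene of these cells, was too bright for its level to be compared. Its deposited signal was 7988 to 9659 on the 6 arrays, close to the highest signal of any probe set on each array, 9028 to 10660, while the array medians ran from 19.8 to 36.3. Its difference after scaling was -0.15 (SE 0.23), and signals this close to the top of the range understate any change. The list of corticotroph and melanotroph identity genes (22 tested, median -0.12) did not pass camera (adjusted p = 0.386). Its members with the smallest p were Nr4a3, given above, its relative Nr4a1 at -0.62 (SE 0.20), the pituitary homeodomain gene Lhx4 at -1.07 (SE 0.36) and Ets1 at 0.50 (SE 0.22). The corticotroph factor gene Tbx19 was at 0.02 (SE 0.14). Adjusted over the list alone, 0 passed without the block and 1, Nr4a1, was lower with it. Tested with fry for changes in either direction, this list and the interferon list each had an adjusted p of 0.00967. Genes of the other pituitary lineages (13 tested, median -0.05, adjusted p = 0.999) included Hesx1 at 1.29 (SE 0.43), Prl at -0.91 (SE 0.45), the immediate early gene Egr1 at -1.16 (SE 0.60) and Esr1 at -0.65 (SE 0.41). Egr1 alone passed adjusted over the list alone, and only in the paired fit. Neuronal markers (21 tested, median -0.18, adjusted p = 0.242) included Rbfox3 at 0.88 (SE 0.25), Celf4 at -0.66 (SE 0.27), Gap43 at -0.37 (SE 0.15) and Nefl at -0.32 (SE 0.17). Immune and endothelial markers (14 tested, median -0.17, adjusted p = 0.612) included Cd8a at -0.46, Cldn5 at -0.63, Cd3e at -0.75 and Eng at -0.44. In neither marker list did a member pass adjusted over the list alone.

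The gene classes that DNA methylation is best known to silence did not pass as groups, and many of their members were too dim to be tested or had no probe set of their own. Of 56 germline genes listed 19 were tested, of which 10 had higher and 9 lower values (median 0.01, camera adjusted p = 0.386). Tex19.1, given above, was followed by Tex101 at 1.80 (SE 0.78), which rests mostly on repeat 2 (0.38, 4.14 and 0.88 in repeats 1 to 3) and has a control signal of 4.47 below the pseudocount, Tuba3b at -0.60 (SE 0.30) and Nxf2 at -0.82 (SE 0.51), and adjusted over the list alone Tex19.1 was higher in both fits and 0 were lower. Of 41 imprinted genes 23 had higher and 18 lower values (median 0.02, adjusted p = 0.438). Nap1l5 differed by -1.16 (SE 0.25), Ndn by -0.94 (SE 0.36), Ddc by 0.53 (SE 0.27) and Igf2 by 0.74 (SE 0.45), and Nap1l5 was the single member that passed adjusted over the list alone. In repeats 1 to 3 Ndn was at -0.48, -0.43 and -1.91 and Igf2 at -0.59, 1.03 and 1.77, so both sizes rest largely on repeat 3. Of 41 X-linked and cancer testis genes listed 11 were tested and 8 had lower values. Their median of -0.29 was the lowest of the 24 lists, at percentile 0.52 of matched random lists, but camera did not call it (adjusted p = 0.217). Its members included Maged2 at -0.72 (SE 0.17), the single member past the threshold adjusted over the list alone, Mageh1 at -0.32 (SE 0.18), Magee1 at -0.29 (SE 0.24) and Tktl1 at 0.87 (SE 0.62). Maged2, Mageh1 and Magee1 had mean scaled signals of 384, 298 and 296 in the control, so they were not silent there. The median of this list is therefore not that of silenced genes alone. Pluripotency genes (14 tested, median 0.01, adjusted p = 0.368) included Klf2 at 0.55 (SE 0.18), which passed adjusted over the list alone in the paired fit only, Gdf3 at 0.89 (SE 0.47), Fgf4 at -0.42 (SE 0.24) and Lin28a at -0.21 (SE 0.24). Tumour suppressors reported as methylated in pituitary tumours (22 tested, median -0.07, adjusted p = 0.612) included Cdh13 at -1.13 (SE 0.29), lower adjusted over the list alone, Cdkn2b at 0.42 (SE 0.20), Rassf3 at -0.45 (SE 0.26) and Sfrp4 at -0.27 (SE 0.21). Cdh13 was at -1.59, -1.56 and -0.25 in repeats 1 to 3, so it differed little in repeat 3. Gdf3 was at 2.25, -0.44 and 0.87, without a common direction.

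The other growth and stress lists, apart from the metallothionein and oxidative stress list given above, did not pass. Cell cycle and replication genes (48 tested, 33 lower, median -0.08, camera adjusted p = 0.932) included Ccnd1 at 0.71 (SE 0.29), which was higher adjusted over the list alone in the paired fit only, Ccne2 at -0.47 (SE 0.29), Top2a at -0.36 (SE 0.23) and Ccnd2 at -0.43 (SE 0.29). Targets of p53 (28 tested, median -0.06, adjusted p = 0.612) included Ak1 at 0.59 (SE 0.22), Ephx1 at 0.35 (SE 0.16), Trp53i11 at 0.42 (SE 0.25) and Rrm2b at -0.40 (SE 0.25). Apoptosis regulators (26 tested, median 0.01, adjusted p = 0.409) included Bik at 0.29, Hrk at 0.36, Casp2 at 0.24 and Cycs at -0.17, with SEs of 0.15 to 0.27. Endoplasmic reticulum and amino acid stress genes (32 tested, 23 lower, median -0.08, adjusted p = 0.353) included Vldlr at -0.71 (SE 0.22), Cth at -0.44 (SE 0.15), Chac1 at -0.31 (SE 0.18) and Hspa5 at -0.29 (SE 0.18), the first 2 of them lower adjusted over the list alone in the paired fit only. Hspa5 was at -0.02, -0.0009 and -0.85 in repeats 1 to 3, so its size rests on repeat 3. Cholesterol synthesis genes (20 tested, median -0.08, adjusted p = 0.963) included Srebf2 at -0.31, Tm7sf2 at -0.20, Hsd17b7 at -0.23 and Mvk at -0.35, heat shock genes (16 tested, median -0.10, adjusted p = 0.612) Hspd1 at -0.34, Hspa1b at 0.44, Hspb1 at -0.27 and Dnaja1 at -0.25. The size for Hspd1 rests mostly on repeat 3 (-0.15, 0.07 and -0.92 in repeats 1 to 3). Hypoxia and glycolysis genes (26 tested, 20 lower, median -0.15, adjusted p = 0.612) included Adm at -0.54 (SE 0.32), the lactate exporter gene Slc16a3 at -1.07 (SE 0.68), Aldoc at 0.28 (SE 0.20) and Pgk1 at -0.33 (SE 0.27); in the paired fit 1 member was higher and 2 lower adjusted over the list alone. Dimmer probe sets had the other sign for Cd8a (1.17), Zbp1 (-0.26), Hells (0.34), Zbtb33 (0.24), Ccnd2 (0.24), Syt7 (0.14), Maged2 (0.12) and Vldlr (0.13). The signs of the medians of the cell cycle, p53, cholesterol and other-lineage lists turned with scaling. For the machinery and p53 lists camera pointed up although median and mean lay below 0, and for the imprinted and apoptosis lists the mean lay below 0 although median and camera pointed up.

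**Figure D3:**
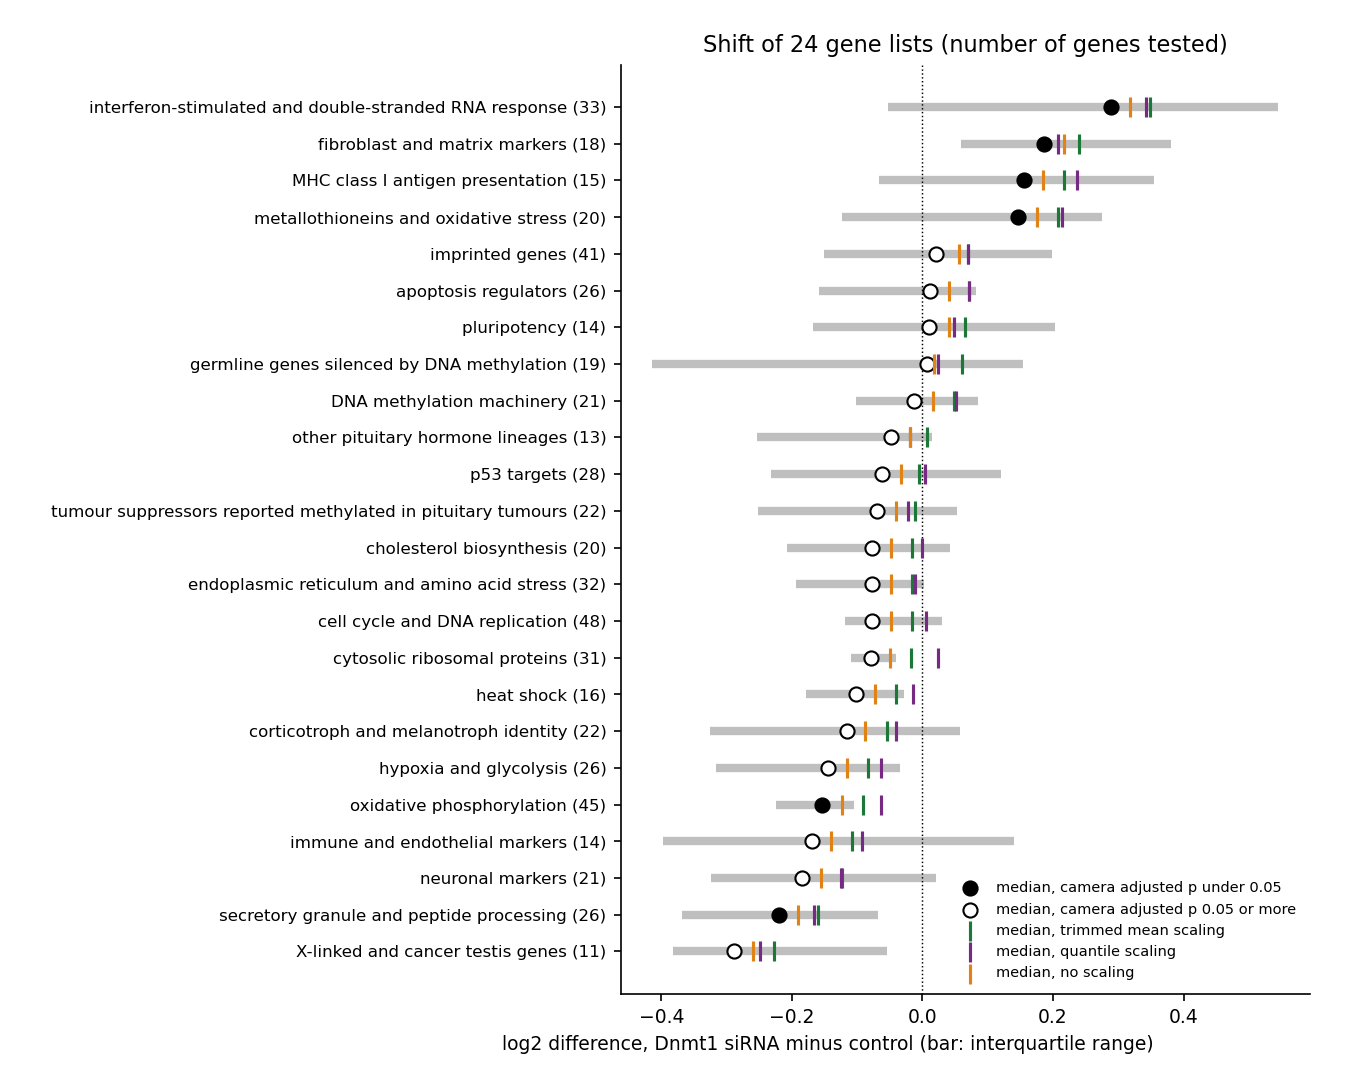
Median log2 difference, knockdown minus control, of the tested members of 24 gene lists, with grey bars for the interquartile range of the members, filled points for lists past the camera threshold with the preset correlation and coloured ticks for the median under 3 other scalings. The interferon list lies farthest up at 0.29 and 6 of 24 points are filled; with an estimated correlation none of the 24 lists passes.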

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

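The count of dim probe sets was chosen after the data were seen.

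Among the 18015 probe sets too dim to be tested, 94 were higher by at least 1.5 times on every knockdown array than on any control array, and 62 were lower by as much. These 94 include no gene named above, and the mean scaled signal of each lies below 16.8, near the background of the arrays. The 156 dim probe sets that parted knockdown from control were no more than other splits gave: the 9 other ways of splitting the 6 arrays parted 122 to 176. Of the 64 control probe sets 0 parted the groups by 1.5 times.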

How the results depend on the processing

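Scaling to a common trimmed mean and every variant of the paired fit were chosen after the result was seen, and the other alternatives before the data were examined. For gene list shifts the robust and the unmoderated variance models were not run, since camera has its own moderation.

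The number of probe sets past the limma threshold, 0, stayed 0 under 9 alternatives. It was 1 with the filter at the 60th percentile, with quantile scaling, with trimmed mean scaling, without cross-hybridising probe sets, with robust eBayes and at adjusted p under 0.10. It was 2 without scaling, 0 to 4 when 1 array was left out and 23 with the block. The cause was not tested.

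The paired count of 23 was 1 with no filter on dim probe sets, 41 with the filter at the 60th percentile, 4 with quantile scaling, 15 without scaling, 3 with trimmed mean scaling, 0 without the trend, 0 in the unmoderated model and 40 at adjusted p under 0.10. It was 41 to 266 when 1 repeat was left out, where only 2 pairs remain. With other pseudocounts, without cross-hybridising probe sets and with robust eBayes it was 19 to 25. All 23 kept their direction under every scaling, which could hardly have come out otherwise. The smallest of their differences was -0.61, for Txnrd1, while the median over all tested probe sets moved only from -0.0555 to 0.0019. The cause of the changes in the count was not tested.

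The 56 separated probe sets became 29 with the pseudocount at the 40th percentile, 212 with no filter, 23 with the filter at the 60th percentile, 34 without scaling, 11 at a fold of 2, 214 when 1.5 times was asked in all 3 pairs (replicate block) and 168 to 243 when 1 array was left out. Under 4 other alternatives there were 50 to 78. By the rule itself, fewer arrays or no filter can hardly lower this count, and a stricter filter or fold can hardly raise it. The cause of the other changes was not tested.

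Dnmt1 was lower under every alternative, at -1.79 to -1.26 when 1 array was left out. Its limma adjusted p passed with the block (-1.54, 0.0211) and, unpaired, without knockdown array 3 (-1.79, 0.0432), and was 0.121 to 1.00 under the other unpaired settings. The paired call was lost with quantile scaling, with trimmed mean scaling, with no filter, without the trend and in the unmoderated model. The unpaired call of Ltb also passed under several settings, with trimmed mean scaling at 0.0208.

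The 6 list shifts became 0 with an estimated correlation and 0 with fry, and in the paired fit 0 with an estimated correlation and 1 with fry. Under the 17 other alternatives there were 5 to 8. The cause was not tested.

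Among values of named genes 7 reversed when 1 array was left out, for 6 genes, Mvk without either of 2 arrays. Pomc ran from -0.35 to 0.12, Hsd17b7 from -0.45 to 0.10, Mvk from -0.74 to 0.21, Rps10 from -0.30 to 0.0023, Rpsa from -0.21 to 0.0090 and Rps28 from -0.28 to 0.04. The cause was not tested.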

Other observations

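The gene order was looked at after the results were seen. In the weighing below, both scaling tests of the interferon and MHC class I lists and of the oxidative phosphorylation and secretory granule lists, all tests of Foxk2, the question of the siRNA duplex and the splits for the unpaired and separated counts were also chosen after the result was seen.

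Tex19.2, Tex19.1 and Foxk2 lie close together on mouse chromosome 11 in the gene order of GRCm38.p6. Tex19.1 is the neighbour of Tex19.2, and 5 genes stand between Tex19.1 and Foxk2. Of these, 4 were tested and lay near 0, with Ogfod3 at -0.16 (SE 0.18), Hexdc at -0.08 (SE 0.22), Cybc1 at 0.04 (SE 0.17) and Narf at -0.12 (SE 0.40). The stretch was picked out after its values were seen, and the close paralogs Tex19.1 and Tex19.2 do not count as separate observations.

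Interferon-stimulated genes such as Irf9, Zbp1 and Ifitm3 and MHC class I genes such as Tapbp had higher values in the knockdown. The joint median was 0.262 over 48 genes. In the interferon list 24 members were higher and 9 lower, the latter including Rsad2, Ifit3 and Ifit1. Scaling does not account for the joint shift, since the joint median was at least 0.291 under the 3 other scalings. Nor does brightness, at percentile 100 of matched random lists, nor 1 repeat alone, with the lowest repeat at 0.157. The control arrays also had 20 nM siRNA over 8 days, so a response that any duplex gives alike would be in both groups. A response to Dnmt1 loss and a response particular to the Dnmt1 duplex cannot be told apart here, with 0 arrays with a second siRNA against Dnmt1. Noise shared by the genes also stays open. The interferon list alone did not pass camera with an estimated correlation (adjusted p = 0.343). That test called 0 of 2 shifted lists in simulated data, which held no noise shared between genes. With fry the interferon list had an adjusted p of 0.372 without the block and 0.044 in the paired fit. For changes in either direction its fry adjusted p was 0.00967. The MHC class I list, with 8 of 15 members higher, did not pass camera with an estimated correlation (adjusted p = 0.633). With fry it did not pass in either fit (adjusted p = 0.420 and 0.441). A second siRNA against Dnmt1 of another sequence would part the first 2, and more repeats would test the last.

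Foxk2 was lower in the knockdown in every repeat on its 3 brightest probe sets. A faulty or cross-hybridising probe set does not account for it, since 3 of the 5 tested Foxk2 probe sets were lower by 0.5 or more on the log2 scale, a bar set after the values were seen, and the 2 that were not are dim. Scaling does not either, with the brightest probe set at -1.34 or lower under the 3 other scalings. An effect of Dnmt1 loss on Foxk2 and off-target binding of the siRNA to the Foxk2 transcript cannot be told apart, with 0 arrays of a second siRNA against Dnmt1 and a siRNA sequence not given in the sources used here.

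Oxidative phosphorylation genes such as Sdhc and Ndufb5 and secretory granule genes such as Sv2a and Rab3a had lower values. Brightness alone does not account for them, with the medians at percentiles 0.35 and 0.02 of matched random lists, but all probe sets with mean deposited signals of 2000 to 4000, where the oxidative phosphorylation median of 2694 lies, had a median difference of -0.105 against -0.153 for that list. The oxidative phosphorylation median reached -0.064 under quantile scaling, where the median over all tested probe sets was -0.0060 in place of -0.0555, so part of its size may come from scaling; camera still passed under the 3 other scalings (adjusted p = 0.00243 to 0.00995), though not with an estimated correlation (0.530 to 0.964) nor without knockdown array 2 (-0.07, adjusted p = 0.154), and how much remains is left open. The secretory granule median stayed at -0.16 or lower under the 3 other scalings, and for both lists a change in these cells and noise shared by the genes stay open. Added control RNA would test the scaling, and more repeats the noise.

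With 6 arrays there are 10 splits into 3 and 3, too few for a share below 0.05. Without the block the real split called 0 probe sets, a count that all 10 splits reach whatever the data, so this comparison decides nothing; the highest other called 1. It had 56 separated probe sets, and 7 of the 10 splits had as many, with 113 at the highest. It had 6 gene lists, reached by 4 of the 10 splits, with 7 at the highest. The splits that keep 2 repeats whole gave 59 to 113 separated probe sets and 1455 to 2245 at an unadjusted p under 0.05, against 1025 for the real split, which points to sample structure by repeat. The nearest comparison is with the 4 splits that part all 3 pairs, since the repeat numbers pair the arrays. Its smallest possible share is 1 of 4, so coming first among these splits cannot exclude chance. In the paired fit the real split called 23 probe sets, and only 1 of the 4 splits, the real one, called as many, with 0 at the highest other. It called 7 lists, again only 1 of 4, with 4 at the highest other. The other splits of this kind had 34 to 44 separated probe sets.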
